A study of Mus musculus with 12 samples.

How the data were processed

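RNA from pulmonary CD11c+ cells of single mice was measured on 12 Affymetrix mouse arrays, 1 array per mouse. Per the labels, lungs were digested with collagenase, CD11c+ cells were taken with magnetic beads, and their purity was above 90% with under 5% lymphocytes. All mice had received Pneumocystis into the trachea, and 3 IFNAR-/- and 3 wildtype mice were taken at day 7 and 3 of each at day 14. Each column of values was matched to its mouse by the sample description, and 0 columns were left without a group.

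The submitters name RMA, a method that corrects background, normalises arrays and summarises probes, without a version. The deposited value of a probe set is a linear ratio, the authors' value divided by about that probe set's own median over the 12 arrays. This division is not stated and was read from the values: the median over the 12 arrays lay within 0.02 of 1 for 100% of the probe sets, against at most 47% for medians over 1 to 3 of the groups. The ratio does not keep how bright a probe set was against other probe sets, so levels and signal over background are not known, and the number of arrays limits the precision. Values were used as log2 ratios with no further normalization.

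The table holds 45101 probe sets with 3 missing values. Of these, 64 are control probe sets, 9160 carry no gene symbol, 932 carry several, and 34945 carry 1 symbol. The Entrez identifiers of 34741 probe sets matched the mouse gene table of assembly GRCm38.p6, which was used for names and for which genes neighbour each other. The log2 ratios of all probe sets with the same single symbol were averaged, which gave 18193 genes, 9183 of them from 1 probe set. Other genes were not analysed here.

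The choices below were made before the data were examined, except where stated. The choice had been to keep the probe set with the highest mean per gene and to leave out dim probe sets. Ratios to a median allow neither, so after the values were seen the mean of all probe sets took their place, with no filter. A linear model with 1 mean for each of the 4 groups was fitted to every gene with limma 3.58.1 in R 4.3.3. It had 8 residual degrees of freedom, and the moderated test added a prior of 3.21 degrees of freedom with a prior standard deviation of 0.171. Tests were two-sided, and p values were adjusted by Benjamini-Hochberg over all 18193 genes, with 0.05 as the threshold. The comparisons were IFNAR-/- minus wildtype at day 7, the same at day 14, the mean of these differences, day 14 minus day 7 within each genotype, and the difference at day 14 minus that at day 7. Comparisons at the same day or within the same genotype share arrays, and all share 1 estimate of the spread.

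There were 28 gene lists, for interferon responses, antigen presentation, mediators, macrophage states, cell cycle, stress and the markers of cell types that the sorted cells could hold. Each was tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 28 lists. Each test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move, on balance, 1 way. Members past the threshold were counted as adjusted over all genes and as adjusted over the list alone. The 5 lists with the largest camera score in each comparison are described, and the others are summarised.

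Genes were named by a rule. It took the 8 largest rises and the 8 largest falls among genes past the threshold whose compared groups of arrays did not overlap, for the mean over both days on neither day; for the change of the genotype difference, overlap was not asked for. It also took up to 4 members with the lowest p of each described list and, in each genotype comparison, Ifnar1, Ifnar2, Irf7, Ifit1, Cxcl10, Ifng, H2-Ab1, Nos2 and Arg1. Genes named outside it are marked as chosen after their values were seen. Calls at both days were compared by a one-sided Fisher exact test.

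Data were simulated for 18193 genes with each gene's residual spread over all 12 arrays, the same for every array. Changes were put into the IFNAR-/- day 7 arrays. The day 7 genotype test called 16% of the genes changed by 0.5 on the log2 scale and 82% of those changed by 1. It called 96% of those changed by 2 and 100% of those changed by 3. Of 17993 unchanged genes 9 were called, and 3 of 100 unchanged lists had p under 0.05. The simulated genes were independent of each other, so this does not check camera on lists whose genes are correlated.

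Alternatives chosen beforehand were quantile normalization applied again, subtraction of each array's median, every probe set tested by itself, a trended and robust variance prior, array weights, the mouse number as a replicate block, a fit of only the arrays compared, each array left out in turn, and a threshold of at least 2-fold. Alternatives chosen after the data were seen were the probe set with the largest standard deviation, genes above the median standard deviation, both arrays that stand apart left out, and control signals as covariates. The covariates were the 5' over 3' signal of the actin and Gapdh control probe sets and the mean of 22 poly-A spike-in probe sets. The number of mouse labels does not pair arrays, since every array came from a different mouse. The genotype labels were also exchanged among arrays: in all 10 splits of 6 arrays for a comparison of single groups, and in 100 relabellings within days, drawn with a fixed seed, for comparisons over both days. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.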

Results

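Gene expression was measured in CD11c+ cells from the lungs of mice infected with the fungus Pneumocystis. CD11c is a surface protein of dendritic cells and of macrophages of the lung. Wildtype mice were compared with IFNAR-/- mice, which lack the receptor for type I interferons, at day 7 and at day 14 after infection, with 3 mice and 3 arrays in each of 4 groups. The labels ask whether type I interferon signalling starts in resident and early recruited CD11c+ cells, and whether it matters for inflammation when clearance begins. Values are log2 ratios of a gene to its median over the 12 arrays, so genes can be compared between arrays but not with each other. Differences are IFNAR-/- minus wildtype or day 14 minus day 7, given with the standard error (SE) of the limma fit and n = 3 arrays per group.

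The first principal component held 40.4% of the variance and the second 16.9%. A pair of arrays stood apart, IFNAR-/- day 7 mouse 3 and IFNAR-/- day 14 mouse 2. Where fits without both change a call, they are given for gene lists by name and for named genes as the number that still passed. The first was the only array with Y-linked transcripts, with Eif2s3y at 2.89 and Xist at -3.98 as log2 ratios. A single male mouse among females would give this. The labels give no sex, and an effect of sex cannot be told apart from other traits of this array. The same array also held high median log2 ratios of lung epithelial (2.39), endothelial (2.43), fibroblast (1.96) and neutrophil (1.53) markers. The second had the widest spread, an interquartile range of 0.581 on the log2 scale. A further array that was kept in those fits, wildtype day 7 mouse 1, was also high in lung epithelial, endothelial and fibroblast markers, at 1.77, 1.74 and 0.76, where the 10 arrays other than it and IFNAR-/- day 7 mouse 3 lay between -0.41 and 0.41. Control probe sets varied as well, as the plot of control probe sets shows. The 5' over 3' signal of actin and Gapdh, a sign of RNA integrity, was -0.446 ± 0.406 (SD, n = 3) on the log2 scale in wildtype day 14 arrays, 0.117 ± 0.05 in IFNAR-/- day 14, 0.112 ± 0.057 in wildtype day 7 and -0.111 ± 0.355 in IFNAR-/- day 7 arrays. The poly-A spike-in signal was -2.47 ± 0.77 (SD, n = 3) in wildtype day 14 arrays, -0.59 ± 1.01 in IFNAR-/- day 14, 1.5 ± 0.67 in wildtype day 7 and -0.54 ± 2.69 in IFNAR-/- day 7 arrays. The 18S ribosomal signal was 1.24 ± 1.13 in wildtype day 14 arrays and 0.07 ± 0.74 in IFNAR-/- day 14 arrays. IFNAR-/- day 7 arrays could lie as low as wildtype day 14 arrays. Mouse 2 was at -0.52 for 5' over 3' and mouse 3 at -3.6 for poly-A. Between genotypes at day 14 only the 18S signal overlapped, at 0.92 in IFNAR-/- mouse 2. There the 5' over 3' signal was -0.239, -0.184 and -0.913 in wildtype and 0.124, 0.064 and 0.164 in IFNAR-/- arrays. The poly-A signal was -2.11, -1.94 and -3.35 against 0.18, -1.73 and -0.21. Wildtype day 7 and day 14 arrays did not overlap in any of these signals. The 5' over 3' and poly-A signals therefore go along with genotype at day 14 and with time in wildtype cells.

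**Figure D1:**
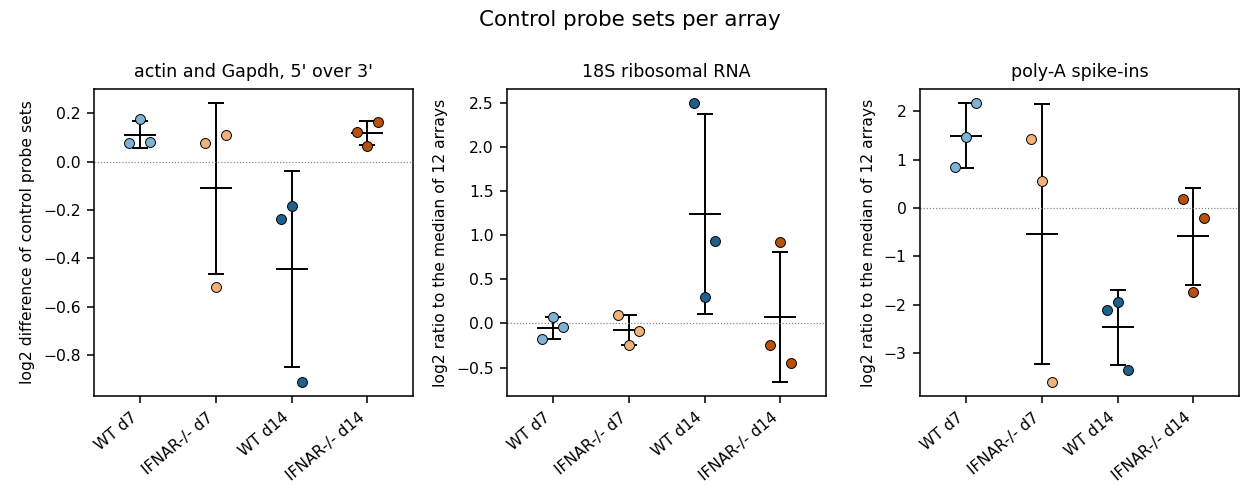
Control probe sets per array, as the log2 5' over 3' difference of actin and Gapdh and as log2 ratios of 18S ribosomal RNA and poly-A spike-ins to the median of 12 arrays; points are single arrays in wildtype (WT) and IFNAR-/- groups at day 7 (d7) and day 14 (d14), with the mean and SD of 3 arrays. The lowest 5' over 3' value, -0.913, is from wildtype day 14 mouse 3.

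Ifnar1, the gene altered in the IFNAR-/- mice, had 2 probe sets. On the first the wildtype arrays held 0.02, 0.63 and -0.02 at day 7 and 0.24, 0.88 and 0.62 at day 14. The IFNAR-/- arrays held -1.34, -1.41 and -0.39 at day 7 and -0.05, -0.64 and 0.00 at day 14, so each IFNAR-/- array lay below every wildtype array of the same day. The difference over both days was -1.03 ± 0.21 (SE), with a limma adjusted p of 0.0257 by Benjamini-Hochberg over all probe sets. On the other the wildtype arrays held 0.14, 0.64 and 0.15 at day 7 and -0.53, -0.73 and -0.39 at day 14. The IFNAR-/- arrays held 0.28, -1.35 and -0.14 at day 7 and 0.26, -1.39 and 0.77 at day 14, with a difference over both days of -0.14 ± 0.36 (SE) and a limma adjusted p of 0.908. As the mean of both probe sets Ifnar1 differed by -0.58 ± 0.25 (SE), with an adjusted p of 0.262 that did not pass. Which part of the gene is altered and whether either probe set lies in it are not given, and a probe set outside that part checks nothing.

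At day 7, IFNAR-/- cells held less of the genes that type I interferon switches on. Oas1a, a sensor of double-stranded RNA, was lower by a log2 difference of -3.50 ± 0.21 (SE), Mx1, an antiviral GTPase whose gene lies within 100 measured genes of Ifnar1, by -2.94 ± 0.30, and Irf7, a transcription factor that amplifies interferon production, by -2.59 ± 0.36. All 47 measured type I interferon-stimulated genes had a difference below 0, with a median of -1.38. Of them 28 fell and 0 rose over all genes, and 42 fell when adjusted over the list alone. Camera gave an adjusted p (Benjamini-Hochberg) of 9.7e-49, and 0.045 with an estimated correlation. Trim30a at -1.59 ± 0.15 and Oas3 at -2.81 ± 0.28 fell as well, while Ifit1, at -0.84 ± 0.44 and a limma adjusted p of 0.474, did not pass. Ifnb1, the gene of interferon beta itself, rose by 3.03 ± 0.34 (limma adjusted p 0.000908).

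**Figure D2:**
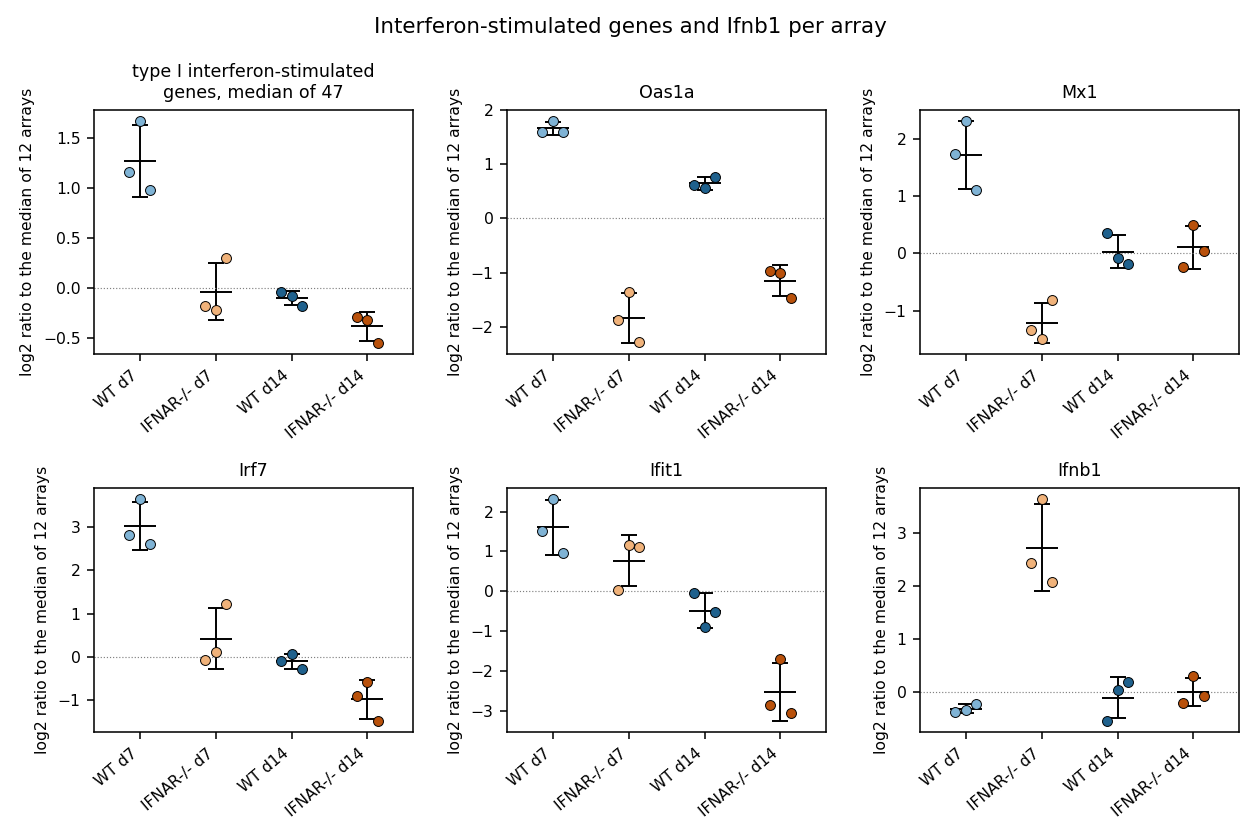
Log2 ratio to the median of 12 arrays (vertical axes) for the median of 47 type I interferon-stimulated genes and for Oas1a, Mx1, Irf7, Ifit1 and Ifnb1; points are single arrays in wildtype (WT) and IFNAR-/- groups at day 7 (d7) and day 14 (d14), with the mean and SD of 3 arrays. Oas1a was lower in all IFNAR-/- arrays than in wildtype arrays of the same day, by -3.50 at day 7 and -1.79 at day 14.

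Genes of antigen presentation and dendritic cells were lower in IFNAR-/- cells at day 7. H2-Aa and H2-Ab1, the chains of an MHC class II molecule, fell by 1.03 ± 0.15 and 0.97 ± 0.15 (SE) on the log2 scale, and the costimulators Cd86 and Cd40 fell by 1.56 ± 0.27 and 2.02 ± 0.39. Of 14 MHC class II genes 7 fell and 0 rose, 10 fell adjusted over the list alone, and the median was -0.61. By camera with Benjamini-Hochberg the adjusted p was 1.4e-11, and 0.045 with an estimated correlation. Among 20 dendritic cell markers 8 fell, 10 adjusted over the list alone, with a median of -0.68, a camera adjusted p of 9.8e-11 and 0.045 with an estimated correlation. They held Kmo at -1.64 ± 0.21, Ccr7, a receptor that guides cells to lymph nodes, at -1.29 ± 0.20, and Batf3 and Itgae, both marks of cross-presenting dendritic cells, at -1.14 ± 0.21 and -1.08 ± 0.20. Of 22 cytotoxic and T helper effectors Il2rb and Icos fell, by 0.98 ± 0.17 and 1.45 ± 0.29, and 11 fell adjusted over the list alone, with a median of -0.59. Gzmb at -2.44 ± 0.57 and Ctla4 at -1.61 ± 0.40 did not pass. Their camera adjusted p was 9.2e-08, and the adjusted p was 0.0872 with an estimated correlation. Of 15 MHC class I genes Psme1, a proteasome activator, fell by 0.62 ± 0.14. Adjusted over the list alone 11 fell and 1 rose, with a median of -0.62, a camera adjusted p of 9.3e-08 and an adjusted p of 0.151 with an estimated correlation. Nlrc5 at -1.29 ± 0.31, Psmb10 at -0.76 ± 0.18 and Psmb8 at -0.85 ± 0.21 did not pass.

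Over all 18193 genes 481 passed at day 7, 235 higher and 246 lower in IFNAR-/- cells. Besides Ifnb1 the largest rises were in Acaa1b, a peroxisomal thiolase, at 4.13 ± 0.67 (SE), BC018473 at 3.25 ± 0.49, the secreted glycoprotein Fstl1 at 3.07 ± 0.44, Adamtsl4 at 2.85 ± 0.16, the cysteine dioxygenase Cdo1 at 2.80 ± 0.43, the potassium channel Kcnj15, within 50 measured genes of Ifnar1, at 2.71 ± 0.22 and Tmem154 at 2.56 ± 0.42. The largest falls besides Oas1a were in Clec1b, a C-type lectin, at -4.10 ± 0.92, Mtmr7 at -3.67 ± 0.41, Trim30d at -3.66 ± 0.36, Ifi209 at -3.61 ± 0.38, Ifi27l2a at -3.61 ± 0.37, Gm4951 at -3.34 ± 0.52 and Ccl7, a chemokine for monocytes, at -3.28 ± 0.55. Arg1, an arginine-degrading enzyme of alternatively activated macrophages, fell by 2.32 ± 0.34. Nos2 at -2.46 ± 0.73, Ifng at -1.64 ± 0.54, Ifnar2 at -0.10 ± 0.20 and Cxcl10 at -0.09 ± 0.45 did not pass. Arrays of the groups did not overlap for 24% of all genes, where chance gives 10%. Of the 32 named genes that passed, 25 passed whichever 1 array was left out. The others were Clec1b, Psme1, Cd86, Cd40, Icos, Batf3 and Itgae. Without both arrays that stand apart 31 of the 32 passed. With the poly-A signal as a covariate 277 genes passed, 234 of them among the 481, and Clec1b, Psme1, Icos and Itgae did not; with the 5' over 3' signal 325 passed, without Clec1b, Psme1 and Icos. Array weights gave more genes in each comparison, 1882 in this one. Without 1 array the number of genes was 210 (IFNAR-/- day 7 mouse 1), 233 (mouse 2), 298 (mouse 3), 243 (wildtype day 7 mouse 1) or 246 (mouse 2).

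Camera called 19 of the 28 lists at day 7, and 4 of these calls held with an estimated correlation; fry called 13. The fourth is the plasmacytoid dendritic cell list, whose median of 15 markers, 5 of them held by another list, was -0.54, with an adjusted p of 0.045 with an estimated correlation. Lower lists besides those above were the interferon-gamma-associated GTPases (-0.70), NK cell (-0.60), monocyte (-0.47), T cell (-0.34), cell cycle (-0.32), alternative activation (-0.27), cytokine (-0.23), interferon signalling (-0.21), chemokine (-0.16) and fungal recognition (-0.06) lists. Alveolar macrophage (0.40), neutrophil (0.32) and fibroblast (0.18) markers were higher. For the 15 calls lost with an estimated correlation, the adjusted p ran from 0.0872 to 0.781. Endothelial (0.33), immediate-early (-0.08), lung epithelial (0.07), neighbours of Ifnar1 (0.06), lipid handling (0.06), lysosome (-0.05), B cell (0.04), erythroid (0.04) and eosinophil, basophil and mast cell (-0.01) lists were not called. For lung epithelial and B cell markers the test pointed down against the median, and the eosinophil list had a mean of 0.08. Without both arrays that stand apart, the fibroblast median was -0.30 and passed in the opposite direction, and the lung epithelial and endothelial medians passed at -0.67 and -0.49. The neutrophil, cytokine and fungal recognition medians, 0.005, -0.22 and -0.06, then did not pass. The interferon-gamma-associated and chemokine medians moved to -1.18 and -0.41. In the lung epithelial, endothelial and fibroblast lists wildtype day 7 mouse 1 stood above the other wildtype day 7 arrays, as given above, so the lower medians are not shown to be shared by the wildtype arrays.

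**Figure D3:**
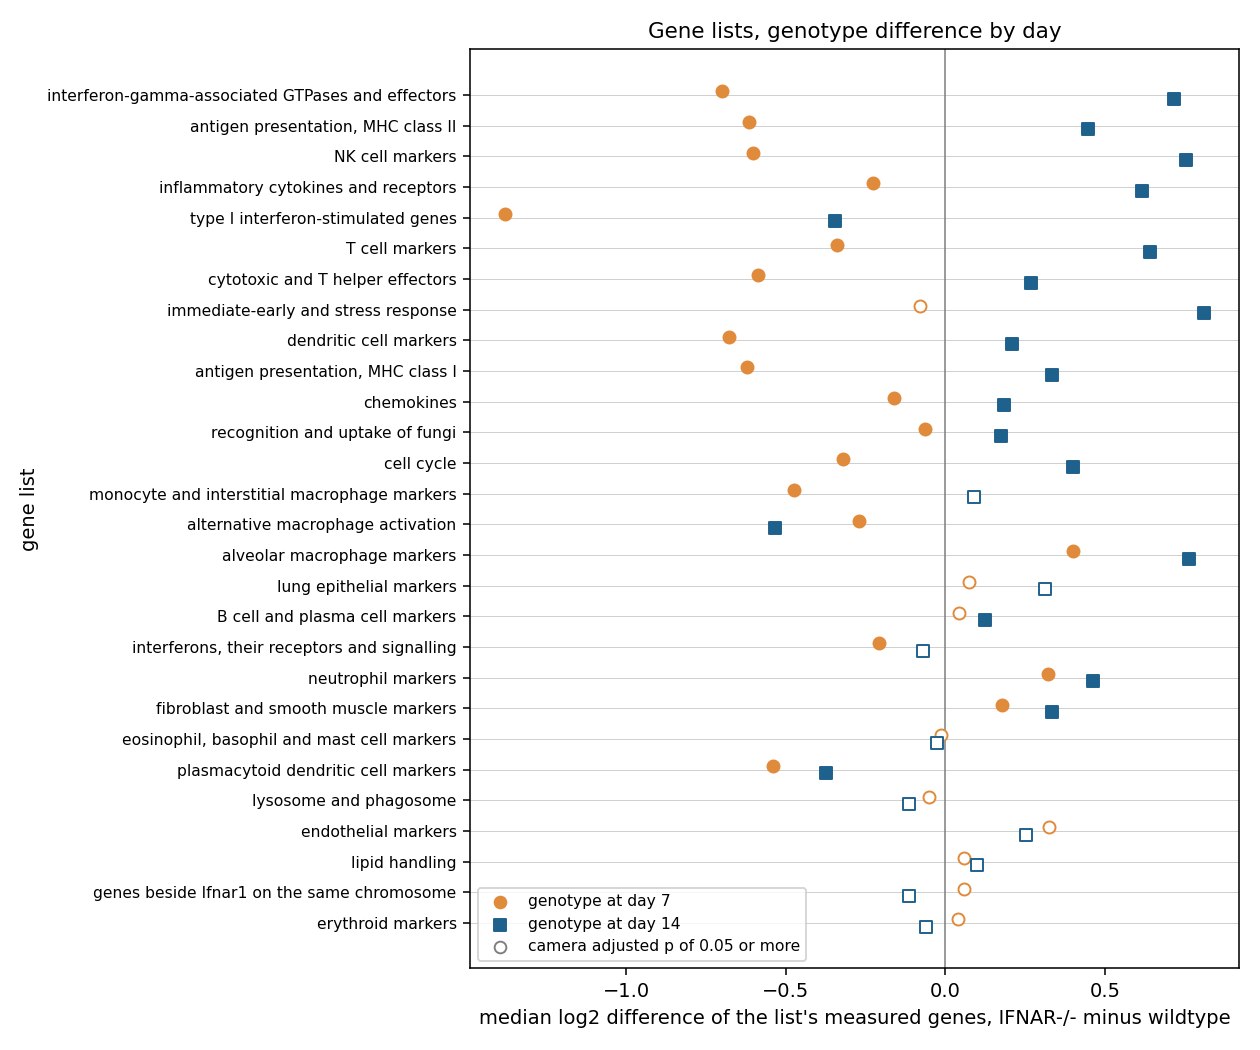
Median log2 difference, IFNAR-/- minus wildtype (horizontal axis), of the measured genes of 28 lists (vertical axis) at day 7 (circles) and day 14 (squares); filled symbols passed camera with its preset correlation. MHC class II genes lay at -0.61 at day 7 and 0.45 at day 14.

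At day 14, IFNAR-/- cells held more transcripts of inflammatory mediators and immediate-early genes than wildtype cells. Il1b and Il1a, both genes of interleukin-1, were higher by a log2 difference of 2.35 ± 0.21 and 2.72 ± 0.34 (SE), Ptgs2, the inducible cyclooxygenase, by 4.39 ± 0.65, and Fasl by 1.72 ± 0.22. Of 25 cytokine genes 9 rose and 0 fell, 10 rose adjusted over the list alone, and the median was 0.62. Camera gave an adjusted p (Benjamini-Hochberg) of 2.9e-09, and the adjusted p was 0.190 with an estimated correlation. Nr4a1, Fosb, Btg2 and Egr1, transcription factors and regulators induced within minutes of a stimulus, rose by 2.77 ± 0.45, 2.28 ± 0.38, 1.40 ± 0.25 and 1.32 ± 0.23. Of 24 immediate-early and stress genes 10 rose, and Ddit3, chosen after its value was seen, fell by 0.58. Adjusted over the list alone 18 rose and 1 fell, with a median of 0.81, a camera adjusted p of 2.1e-10 and an adjusted p of 0.247 with an estimated correlation. The 5' over 3', poly-A and 18S signals of both groups are given above. In wildtype cells the immediate-early and cytokine lists were lower at day 14 than at day 7 by camera. Neither of these calls held with an estimated correlation.

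Lymphocyte markers and MHC class II genes were also higher in IFNAR-/- cells at day 14. Cd3g, a chain of the T cell receptor complex, rose by 1.89 ± 0.40 (SE), Cd8b1, a chain of the CD8 co-receptor, by 1.95 ± 0.44, Lat by 0.90 ± 0.20 and Cd27 by 0.88 ± 0.20. Of 21 T cell markers 7 rose and 0 fell, 13 rose adjusted over the list alone, and the median was 0.64. By camera with Benjamini-Hochberg the adjusted p was 3.3e-09, and the adjusted p was 0.247 with an estimated correlation. Ifng, the gene of interferon gamma, rose by 2.32 ± 0.54. Of 14 MHC class II genes H2-DMb2, H2-Oa, Cd74 and Ciita rose, by 1.42 ± 0.26, 1.82 ± 0.36, 0.45 ± 0.09 and 0.94 ± 0.22, and 11 rose adjusted over the list alone. Their median was 0.45, with a camera adjusted p of 4.2e-07 and an adjusted p of 0.190 with an estimated correlation; H2-Ab1, at 0.50 ± 0.15, did not pass. Of 34 cell cycle genes Rrm2 and Mcm5 rose, by 1.32 ± 0.30 and 0.73 ± 0.18, and 9 rose adjusted over the list alone, while Mki67 at 1.12 ± 0.29 and Cdk1 at 0.66 ± 0.18 did not pass. The list had a median of 0.40, a camera adjusted p of 9.3e-09 and an adjusted p of 0.324 with an estimated correlation, and the median was 0.66 without both arrays that stand apart.

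Type I interferon-stimulated genes were lower at day 14 too, with a median of -0.34, which was -0.21 without wildtype day 14 mouse 1 and -0.23 without IFNAR-/- day 14 mouse 3. Ifit1 fell by 2.04 ± 0.44 (SE). Oas1a at -1.79, Usp18 at -1.62, Ifi27l2a at -2.10 and Slfn8 at -1.48, chosen after their values were seen, fell with it, and Ly6e, chosen likewise, rose by 0.83. Adjusted over the list alone 11 of 47 fell and 2 rose. The camera adjusted p (Benjamini-Hochberg) was 0.00134, and the adjusted p was 0.565 with an estimated correlation and 0.225 with fry. With the poly-A signal as a covariate the median was -0.13 and did not pass. Irf7 at -0.88 ± 0.36 and Cxcl10 at 1.74 ± 0.45 did not pass.

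In all, 917 genes passed at day 14, 318 higher and 599 lower in IFNAR-/- cells. Large rises were in the ubiquitin-like modifier Ubd at 4.58 ± 0.92 (SE), Lcn2, which binds bacterial siderophores, at 3.6 ± 0.78, the scavenger receptor Marco at 3.59 ± 0.70, the protease Mmp2 at 3.49 ± 0.53, Fabp1 at 3.09 ± 0.75, Cbln1 at 2.98 ± 0.48 and the zinc transporter Slc39a2 at 2.93 ± 0.35. Large falls were in Fbp1, an enzyme of gluconeogenesis, at -5.20 ± 1.25, Bex1 at -4.82 ± 1.07, Ddx4 at -3.50 ± 0.39, Cd163, the haemoglobin scavenger receptor, at -3.33 ± 0.54, Slc36a2 at -3.21 ± 0.32, Tmem26 at -3.16 ± 0.46, Rbp4, the carrier of retinol, at -3.07 ± 0.77 and Zfp874a at -2.53 ± 0.38. Nos2 at 1.79 ± 0.73, Ifnar2 at -0.33 ± 0.20 and Arg1 at -0.32 ± 0.34 did not pass. Arrays did not overlap for 23.4% of all genes, where chance gives 10%. With the 5' over 3' signal as a covariate, chosen after the data were seen, 37 genes passed, 36 of them among the 917. All 917 kept their direction and a median of 92.7% of their difference, while the standard error for the same residual spread was 1.34 times larger. Of the 35 named genes that passed, Slc39a2, Ddx4, Slc36a2, Il1b and Il1a passed with this covariate, and all but Fabp1, Rbp4, Mcm5 and Ifit1 passed with the poly-A signal. Without 1 array the number was 555 (IFNAR-/- day 14 mouse 1), 515 (mouse 3), 384 (wildtype day 14 mouse 2) or 384 (mouse 3), and 17 of the 35 named genes passed whichever 1 array was left out. The other 18 were Ubd, Lcn2, Marco, Fabp1, Fbp1, Bex1, Rbp4, H2-Oa, Cd74, Ciita, Rrm2, Mcm5, Cd3g, Lat, Cd8b1, Cd27, Ifit1 and Ifng. Without both arrays that stand apart 27 of the 35 named genes passed.

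Camera called 19 lists at day 14. Higher lists besides those above were the alveolar macrophage (0.76), NK cell (0.75), interferon-gamma-associated GTPase (0.72), neutrophil (0.46), MHC class I (0.33), fibroblast (0.33), cytotoxic and T helper (0.27), dendritic cell (0.21), chemokine (0.18), fungal recognition (0.17) and B cell (0.13) lists, and alternative activation (-0.53) and plasmacytoid dendritic cell (-0.38) lists were lower. None of the 19 calls held with an estimated correlation, where the adjusted p ran from 0.190 to 0.703, and 5 were called by fry. Lung epithelial (0.31), endothelial (0.25), neighbours of Ifnar1 (-0.11), lysosome (-0.11, with a mean of 0.04 and a test pointing up), lipid handling (0.10), monocyte (0.09), interferon signalling (-0.07), erythroid (-0.06) and eosinophil, basophil and mast cell (-0.03) lists were not called. The alternative activation median did not pass without both arrays that stand apart, at -0.36. The NK cell, interferon-gamma-associated, cytotoxic and T helper, and chemokine medians then moved to 0.50, 0.47, 0.15 and 0.10 and passed.

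**Figure D4:**
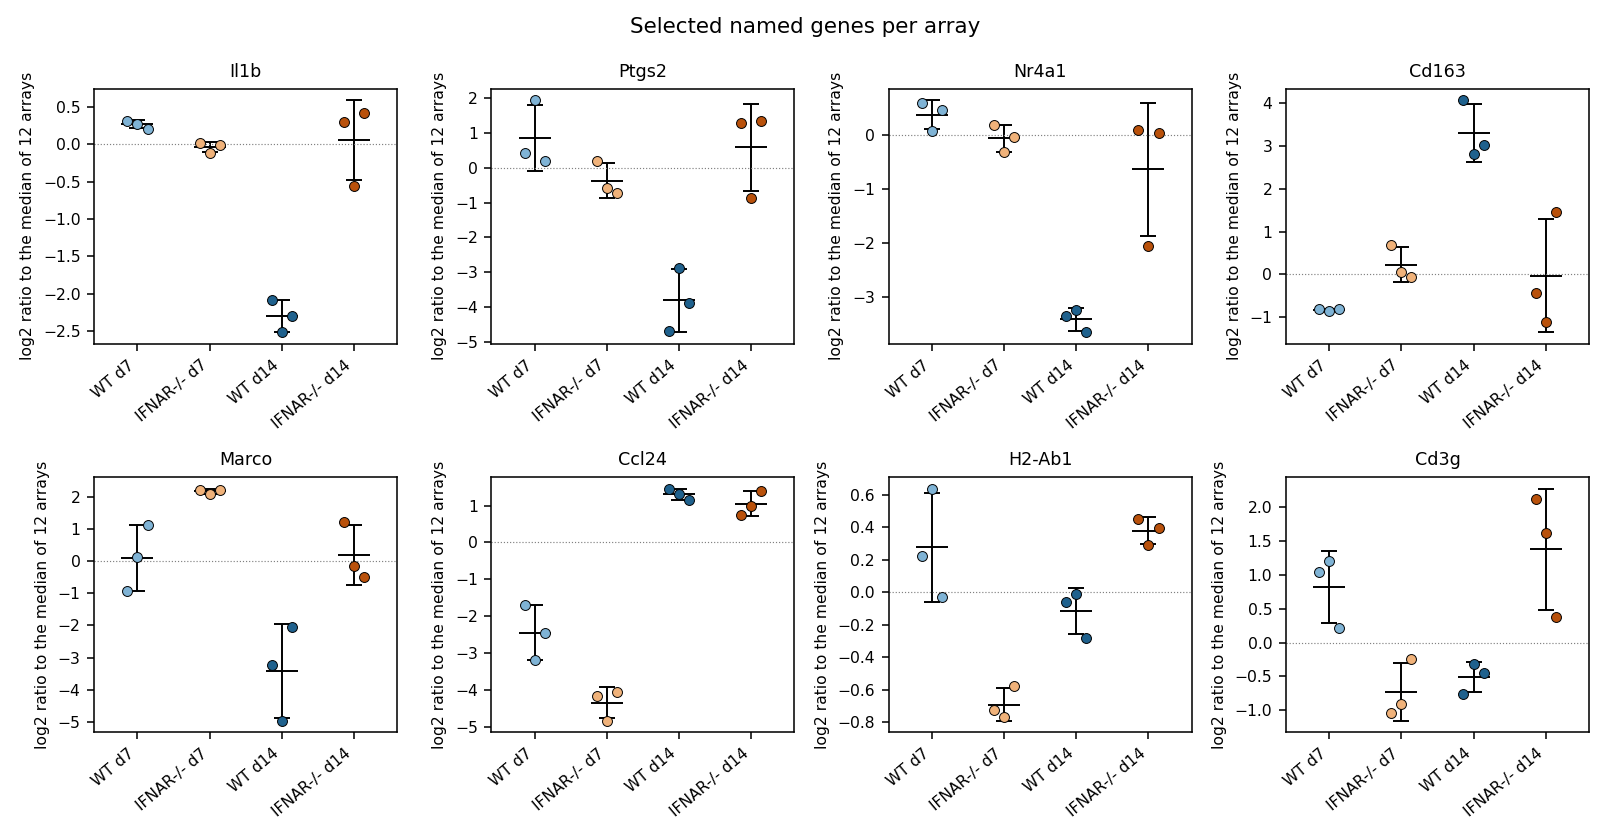
Log2 ratio to the median of 12 arrays (vertical axes) for Il1b, Ptgs2, Nr4a1, Cd163, Marco, Ccl24, H2-Ab1 and Cd3g; points are single arrays in wildtype (WT) and IFNAR-/- groups at day 7 (d7) and day 14 (d14), with the mean and SD of 3 arrays. Between the genotypes at day 14, Il1b differed by 2.35 and Cd163 by -3.33.

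Calls of the same direction were shared between days. Of the genes called at both days, 34 were lower at both, where 8.1 are expected by chance (one-sided Fisher exact p 1.4e-12), and 17 were higher at both, against 4.1 (p 8.8e-07). In opposite directions, 16 were lower at day 7 and higher at day 14, against 4.3 (p 7.3e-06), and 8 were higher and then lower, against 7.7 (p 0.512). The days share no arrays but share 1 estimate of the spread, and genes are not independent.

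As the mean over both days, 762 genes passed, 309 higher and 453 lower in IFNAR-/- cells. Oas1a fell by 2.64 ± 0.15 (SE), Ifi27l2a was at -2.86 ± 0.26, Slfn8 at -1.99 ± 0.19 and Oas3 at -1.92 ± 0.20. Of 47 interferon-stimulated genes 28 fell, 37 adjusted over the list alone. Their median was -0.87, with a camera adjusted p (Benjamini-Hochberg) of 1.9e-31 and an adjusted p of 0.175 with an estimated correlation. Of 15 plasmacytoid dendritic cell markers, whose cells are a main source of type I interferon, 6 fell, 7 adjusted over the list alone. They held Klk1 at -1.30 ± 0.23, Bst2, itself an interferon-stimulated gene, at -0.99 ± 0.20, Smim5 at -0.46 ± 0.10 and Siglech at -0.41 ± 0.09, and the median was -0.39, with a camera adjusted p of 6.3e-08 and 0.0262 with an estimated correlation. Another list holds 5 of these 15 markers, so the list does not stand for these cells alone. Of 19 alveolar macrophage markers 6 rose, 9 adjusted over the list alone, among them Fabp1 at 2.86 ± 0.53, Marco at 2.83 ± 0.49, Krt19 at 1.84 ± 0.39 and Slc39a2 at 1.32 ± 0.25, with a median of 0.37. Of 19 alternative activation genes 5 fell, 8 adjusted over the list alone, with a median of -0.41: Pdcd1lg2 at -1.92 ± 0.31, Arg1 at -1.32 ± 0.24, Ccl22 at -0.95 ± 0.20, Clec7a, the receptor for fungal beta-glucan, at -0.36 ± 0.06, and Ccl24, chosen after its value was seen, at -1.08. Of 24 immediate-early genes Ier2, Egr1 and Zfp36 rose, by 1.15 ± 0.25, 1.07 ± 0.17 and 0.61 ± 0.13, and Ddit3 fell by 0.56 ± 0.10; adjusted over the list alone 10 rose and 1 fell, with a median of 0.37. These 3 lists had camera adjusted p values of 9.7e-07, 1.0e-05 and 2.4e-06, and each an adjusted p of 0.436 with an estimated correlation.

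Among genes whose arrays overlapped on neither day, the largest rises of this mean besides Fabp1 and Marco were in Fstl1 at 2.84 ± 0.31 (SE), BC018473 at 2.49 ± 0.35, Kcnj15 at 2.14 ± 0.16, the cytokine gene Tnf at 2.07 ± 0.29, Fam241b at 1.96 ± 0.11 and the neutrophil chemokine Cxcl1 at 1.94 ± 0.36. The largest falls besides Ifi27l2a and Oas1a were in Clec1b at -3.09 ± 0.65, Ddx4 at -2.81 ± 0.27, the monocyte chemokine Ccl12 at -2.68 ± 0.40, Trim30d at -2.64 ± 0.26, Tmem26 at -2.53 ± 0.32 and Mtmr7 at -2.50 ± 0.29. Irf7 at -1.74 ± 0.26 and Ifit1 at -1.44 ± 0.31 fell, while Cxcl10 at 0.82 ± 0.32, Ifng at 0.34 ± 0.38, Nos2 at -0.34 ± 0.52, H2-Ab1 at -0.24 ± 0.11 and Ifnar2 at -0.22 ± 0.14 did not pass. Camera called 8 lists, 5 higher and 3 lower, the others being cytokines (0.35), neutrophil (0.44) and fibroblast (0.30) markers, all higher, with an adjusted p of 0.436, 0.436 and 0.938 with an estimated correlation. The fibroblast median did not pass without both arrays that stand apart, at 0.004, and the cell cycle median then passed, at 0.12. Of 34 named genes that passed, 25 passed whichever 1 array was left out. The others were Clec1b, Ccl22, Ier2, Zfp36, Krt19, Bst2, Smim5, Siglech and Ifit1. Without both arrays that stand apart 32 of the 34 passed. With the 5' over 3' signal as a covariate 493 genes passed, 458 of them among the 762, without Clec1b, Ier2, Zfp36, Smim5, Siglech and Ifit1. Without 1 array the number was 376 (IFNAR-/- day 7 mouse 1), 502 (IFNAR-/- day 14 mouse 1), 495 (wildtype day 7 mouse 1), 501 (wildtype day 7 mouse 2) or 493 (wildtype day 14 mouse 2).

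From day 7 to day 14 in wildtype cells, interferon-stimulated, immediate-early and alveolar macrophage genes fell. Oas3 fell by 3.14 ± 0.28 (SE), Irf7 by 3.12 ± 0.36, and Ifih1 and Ddx58, sensors of viral RNA, by 1.5 ± 0.15 and 1.21 ± 0.14. Of 47 interferon-stimulated genes 36 fell and 0 rose, 45 adjusted over the list alone, with a median of -1.47. Of 19 alveolar macrophage markers 13 fell, 15 adjusted over the list alone, with a median of -1.73, among them Krt19 at -4.05 ± 0.55, Slc39a2 at -3.51 ± 0.35, the lipid droplet protein gene Cidec at -3.46 ± 0.51 and the lipase Lpl at -2.27 ± 0.27. Of 24 immediate-early and stress genes 17 fell, 20 adjusted over the list alone, with a median of -1.02, among them Nr4a1 at -3.77 ± 0.45, Fosb at -3.17 ± 0.38 and Btg2 at -2.35 ± 0.25, and Hmox1, which degrades haem, rose by 1.16 ± 0.17. Of 25 cytokine genes 9 fell, 14 adjusted over the list alone, with a median of -0.96: Il18 at -3.16 ± 0.40, Il1b at -2.57 ± 0.21, Osm at -2.52 ± 0.35 and Il1a at -2.48 ± 0.34 were among them, and Il33 rose by 3.11 ± 0.69. Of 34 cell cycle genes Mcm6 fell by 0.83 ± 0.23, 8 fell adjusted over the list alone, and the median was -0.53; Mcm5 at -0.64 ± 0.18, Tpx2 at -0.46 ± 0.14 and Nusap1 at -0.43 ± 0.13 did not pass. The camera adjusted p values (Benjamini-Hochberg) of these 5 lists were 1.0e-35, 1.9e-14, 3.4e-13, 2.1e-08 and 2.8e-08. For the first 4 the adjusted p was 0.178 with an estimated correlation, and for cell cycle it was 0.351 with an estimated correlation. The 5' over 3' and poly-A signals of the wildtype day 14 arrays are given above.

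In wildtype cells 1451 genes passed, 705 higher and 746 lower at day 14. The largest rises besides Il33 were in Rbp4 at 5.07 ± 0.77 (SE), Cd163 at 4.12 ± 0.54, the eosinophil chemokine Ccl24 at 3.76 ± 0.33, Rnase2a at 3.57 ± 0.94, Timp1 at 3.27 ± 0.40, Gja1 at 3.06 ± 0.58 and Ddx4 at 2.96 ± 0.39. The largest falls besides Krt19 and Nr4a1 were in Hspa1b and Hspa1a, heat shock genes of the immediate-early and stress list, at -5.37 ± 1.14 and -4.91 ± 1.14, Ptgs2 at -4.66 ± 0.65, Ifit3 at -3.88 ± 0.58, Ereg at -3.83 ± 0.93 and Fabp1 at -3.80 ± 0.75. Camera called 21 lists, 19 lower and 2 higher; the higher ones were alternative activation (1.22) and erythroid (0.18) markers. The lower ones included endothelial (-1.07), lung epithelial (-1.05) and fibroblast (-0.55) markers, in which wildtype day 7 mouse 1 stood above the other wildtype day 7 arrays. None held with an estimated correlation, where the adjusted p ran from 0.178 to 0.466, and 12 were called by fry. Arrays did not overlap for 31.1% of all genes, where chance gives 10%. With the 5' over 3' signal as a covariate 154 genes passed, 146 of them among the 1451, and of the 31 named genes 19 passed, without Rbp4, Rnase2a, Il33, Gja1, Hspa1b, Hspa1a, Ptgs2, Ifit3, Ereg, Fabp1, Mcm6 and Cidec. All 1451 kept their direction and a median of 91% of their difference, with a standard error 1.34 times larger for the same residual spread. With the poly-A signal as a covariate 864 passed, 368 of them among the 1451, with 21 of the named genes, without Rnase2a, Il33, Gja1, Hspa1b, Hspa1a, Ptgs2, Ereg, Fabp1, Osm and Mcm6. Of 31 named genes that passed, 25 passed whichever 1 array was left out; the others were Rnase2a, Il33, Hspa1b, Hspa1a, Ereg and Mcm6. Without both arrays that stand apart, which enter here only through the shared estimate of the spread, 2428 genes passed. Without 1 array the number was 716 (wildtype day 7 mouse 1), 786 (mouse 2), 889 (mouse 3), 860 (wildtype day 14 mouse 2) or 773 (mouse 3).

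From day 7 to day 14 in IFNAR-/- cells, MHC class II, dendritic cell and T cell genes rose, and alveolar macrophage markers fell. H2-DMa rose by 1.20 ± 0.14 (SE), H2-Aa by 1.18 ± 0.15, H2-Ab1 by 1.07 ± 0.15 and Ciita, the master regulator of MHC class II, by 1.41 ± 0.22. Of 14 MHC class II genes 10 rose and 0 fell, 10 adjusted over the list alone, with a median of 1.12. Of 20 dendritic cell markers 10 rose and 0 fell, with 11 up and 1 down adjusted over the list alone and a median of 0.71, among them Ccl22 at 3.36 ± 0.28, Ccl17 at 3.25 ± 0.49, Batf3 at 1.78 ± 0.21 and Kmo at 1.32 ± 0.21. Of 21 T cell markers 12 rose, 16 adjusted over the list alone, with a median of 0.63, among them Thy1 at 3.07 ± 0.46, Cd8b1 at 2.89 ± 0.44, Cd3d at 2.08 ± 0.39 and Lat at 1.07 ± 0.20; Cd2, chosen after its value was seen, fell by 1.59. Of 22 cytotoxic and T helper effectors 7 rose, 12 adjusted over the list alone, with a median of 0.44, among them Cxcr6 at 2.93 ± 0.38, Ifng at 2.56 ± 0.54, Cxcr3 at 1.12 ± 0.19 and Il2rb at 1.01 ± 0.17. Of 19 alveolar macrophage markers 9 fell, 13 adjusted over the list alone, with a median of -1.24, among them Cidec at -3.71 ± 0.51, Krt19 at -3.09 ± 0.55, Lpl at -1.40 ± 0.27 and Cd9 at -0.85 ± 0.17. The camera adjusted p values (Benjamini-Hochberg) in this order were 2.0e-07, 1.5e-05, 1.2e-07, 4.2e-06 and 5.2e-07. With an estimated correlation the adjusted p was 0.333 for MHC class II, dendritic and cytotoxic lists and 0.359 for T cell and alveolar macrophage lists.

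In IFNAR-/- cells 2244 genes passed, 743 higher and 1501 lower at day 14. The largest rises were in Ccl24 at 5.40 ± 0.33 (SE), Ubd at 4.10 ± 0.92, Ocstamp at 3.92 ± 0.47, Timp1 at 3.92 ± 0.40, the inducible nitric oxide synthase Nos2 at 3.63 ± 0.73, Alpk2 at 3.51 ± 0.31, Il12a, a subunit of interleukin-12, at 3.47 ± 0.45 and Pdcd1lg2 at 3.39 ± 0.44. The largest falls besides Cidec were in Acaa1b at -5.84 ± 0.67, Bex1 at -3.87 ± 1.07, Vstm2a at -3.81 ± 0.54, Cdo1 at -3.69 ± 0.43, Flvcr2 at -3.64 ± 0.65, Ereg at -3.56 ± 0.93 and Agmo at -3.39 ± 0.67. Camera called 19 lists, 11 higher and 8 lower. None held with an estimated correlation, where the adjusted p ran from 0.333 to 0.686, and 9 were called by fry. The epithelial (-0.74), endothelial (-1.06) and fibroblast (-0.59) lists were among the lower ones; without both arrays that stand apart their medians, 0.02, -0.19 and -0.002, did not pass. The interferon-stimulated (-0.25), lipid handling (-0.59) and Ifnar1 neighbour (-0.22) lists were also lower and did not pass without these arrays, at -0.09, -0.41 and -0.08. B cell markers, not called at 0.22, then passed at 0.25, and the cell cycle list, higher at 0.26, moved to 0.47. Arrays did not overlap for 34% of all genes, where chance gives 10%. Of 35 named genes that passed, 32 passed whichever 1 array was left out; the others were Ubd, Bex1 and Ereg. Bex1 did not pass with the 5' over 3' signal as a covariate either. Without both arrays that stand apart 1136 genes passed, with 29 of the 35 named genes. Without 1 array the number was 1094 (IFNAR-/- day 7 mouse 1), 1486 (mouse 2), 1385 (mouse 3), 1436 (IFNAR-/- day 14 mouse 2) or 1450 (mouse 3).

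The genotype difference itself changed between the days for MHC class II, T cell and interferon genes. For H2-Ab1, H2-Aa, H2-DMa and Cd74 the difference was higher at day 14 than at day 7 by 1.46 ± 0.22, 1.41 ± 0.21, 1.19 ± 0.20 and 0.86 ± 0.13 (SE). Of 14 MHC class II genes 9 changed upward, 13 adjusted over the list alone, with a median change of 1.44. Of 21 T cell markers 7 changed upward, 14 adjusted over the list alone, with a median of 1.09, among them Thy1 at 3.55 ± 0.65, Cd3g at 3.44 ± 0.57, Cd8b1 at 3.37 ± 0.62 and Cd3d at 3.05 ± 0.56. Of 47 interferon-stimulated genes 11 changed upward, 27 adjusted over the list alone, with a median of 1.10, among them Mx1 at 3.02 ± 0.42, Lgals3bp at 2.00 ± 0.34, Eif2ak2 at 1.74 ± 0.29 and Oas1a at 1.71 ± 0.29. Of 21 interferon-gamma-associated genes Cxcl9, Socs1, Irf8 and Ciita changed upward, by 4.82 ± 0.74, 2.07 ± 0.40, 1.77 ± 0.35 and 1.62 ± 0.30, and 14 did adjusted over the list alone, with a median of 1.60. Of 34 cell cycle genes Cdk1 changed, by 1.15 ± 0.26, and 12 did adjusted over the list alone, with a median of 0.68; Rrm2 at 1.74 ± 0.43, Melk at 1.37 ± 0.38 and Plk1 at 1.09 ± 0.32 did not pass. The camera adjusted p values (Benjamini-Hochberg) in this order were 5.7e-15, 3.0e-13, 2.4e-18, 2.1e-10 and 1.2e-12. The adjusted p with an estimated correlation was 0.0671, 0.0812, 0.113, 0.196 and 0.196 in the same order.

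By this test of the change, 451 genes passed, 208 upward and 243 downward. The largest upward changes besides Cxcl9 and Thy1 were in Ubd at 6.68 ± 1.30 (SE), Ptgs2 at 5.61 ± 0.92, the cytotoxic granule genes Nkg7 and Gzmb at 4.22 ± 0.74 and 4.15 ± 0.81, Ifng at 3.96 ± 0.76 and Cxcr6 at 3.82 ± 0.54. The largest downward changes were in Bex1 at -7.33 ± 1.52, Cd163 at -4.38 ± 0.76, Adamtsl4 at -3.22 ± 0.23, Slc36a2 at -3.11 ± 0.45, Ifnb1 at -2.92 ± 0.48, Npl at -2.82 ± 0.40, Dennd4c at -2.54 ± 0.54 and the complement receptor C5ar1 at -2.54 ± 0.30. Nos2 at 4.25 ± 1.03, Arg1 at 2.00 ± 0.48, Cxcl10 at 1.83 ± 0.64, Irf7 at 1.72 ± 0.51, Ifit1 at -1.20 ± 0.63, Ifnar1 at 0.80 ± 0.50 and Ifnar2 at -0.23 ± 0.28 did not pass. Camera called 15 lists, all upward. None held with an estimated correlation, where the adjusted p ran from 0.0671 to 0.691, and 13 were called by fry. Without both arrays that stand apart 6 more lists passed: lung epithelial (0.83), neutrophil (0.70), fibroblast (0.64), endothelial (0.63), B cell (0.25) and interferon signalling (0.25) genes. In the lung epithelial, fibroblast and endothelial lists wildtype day 7 mouse 1, kept in this fit, stood above the other wildtype day 7 arrays. With the 5' over 3' signal as a covariate 3 genes passed, all among the 451, and with the poly-A signal 184, 129 of them among the 451. Under the first covariate all 451 kept their direction and a median of 93.2% of their change, with a standard error 1.33 times larger for the same residual spread, and of the 31 named genes Adamtsl4 and Slc36a2 passed. With the poly-A signal 21 of them passed. Of these 31 genes 18 passed whichever 1 array was left out. The others were Ubd, Nkg7, Gzmb, Ifng, Thy1, Bex1, Dennd4c, Ciita, Socs1, Irf8, Cdk1, Cd3d and Cd8b1. Without both arrays that stand apart 30 of the 31 passed. Without 1 array the number was 168 (IFNAR-/- day 7 mouse 1), 138 (mouse 2), 262 (IFNAR-/- day 14 mouse 3), 180 (wildtype day 7 mouse 1), 167 (mouse 2), 230 (wildtype day 14 mouse 2) or 222 (mouse 3).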

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

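Fits with a control signal as a covariate and fits without both arrays that stand apart were chosen only after the data were seen. The count of T and NK cell markers and the comparison of B cell markers with MHC class II genes address patterns found in the data. They were therefore chosen after these patterns were seen. The other tests of this part were not.

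The results here drew attention because the difference between genotypes was not the same at both days, by a limma test of the change itself, day 14 minus day 7, with 3 arrays per group. It called 451 genes. Of 100 relabellings within days, the real one included, 1 gave as many, and the highest of the others gave 133. These relabellings also remove the genotype difference common to both days, so they do not test the change alone. Exchanging the genotypes at day 14 alone, which was not drawn, would turn this test into that of the mean over both days. That mean called 762 genes, more than 451, so chance is not excluded for this count. With the 5' over 3' signal as a covariate 3 genes passed. The called genes held a median of 93.2% of their change, and the standard error for the same residual spread was 1.33 times larger. The covariate also takes a residual degree of freedom, and what each part adds to the lost calls was not tested.

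Among gene lists called by camera the median change was 1.602 for interferon-gamma-associated GTPases, 1.439 for MHC class II, 1.366 for NK cell, 1.19 for cytokine, 1.096 for type I interferon-stimulated, 1.091 for T cell and 1.031 for cytotoxic and T helper genes. It was 0.893 for immediate-early, 0.88 for dendritic cell, 0.844 for MHC class I, 0.799 for chemokine, 0.741 for fungal recognition, 0.684 for cell cycle, 0.665 for monocyte and 0.374 for alveolar macrophage genes. With an estimated correlation the adjusted p of these calls ran from 0.0671 to 0.691, so none passed.

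Among genes the change was 6.683 for Ubd, 5.607 for Ptgs2, 4.823 for Cxcl9, 4.224 for Nkg7, 4.15 for Gzmb, 3.956 for Ifng, 3.819 for Cxcr6 and 3.551 for Thy1. It was -7.332 for Bex1, -4.377 for Cd163, -3.223 for Adamtsl4, -3.111 for Slc36a2, -2.92 for Ifnb1, -2.817 for Npl, -2.539 for Dennd4c and -2.536 for C5ar1. Among interferon genes it was 3.017 for Mx1, 1.739 for Eif2ak2, 1.998 for Lgals3bp, 1.705 for Oas1a, 1.624 for Ciita, 2.073 for Socs1 and 1.772 for Irf8. It was 0.858 for Cd74, 1.464 for H2-Ab1, 1.413 for H2-Aa, 1.194 for H2-DMa, 1.154 for Cdk1, 3.437 for Cd3g, 3.051 for Cd3d and 3.366 for Cd8b1.

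Immediate-early and stress genes were higher in IFNAR-/- than wildtype arrays at day 14, with a median of 0.811. The median was 0.808 with the 5' over 3' signal as a covariate and 0.771 with the poly-A signal. It was 1.124 without the array of widest spread, and each had a camera p under 0.05. The last value argues against that array as the whole cause. The slopes of these covariates rest on differences within groups, since the model holds 1 mean per group. Neither control signal overlapped between genotypes at day 14, so the genotypes share no range of either signal there. These covariates cannot decide on RNA integrity or the poly-A signal as a cause, and both stay open. With an estimated correlation the p was 0.103 and 0.0993 under these covariates and 0.00309 without that array. How the wildtype day 14 lungs were handled beside the others is not given in the labels, and a difference there stays open. An effect of the genotype stays open too, as a hypothesis.

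T and NK cell markers moved from lower at day 7 to higher at day 14 in IFNAR-/- against wildtype arrays. Of 37 markers, 6 of them held by another list, 35 (94.6%) had a higher difference at day 14, Cd3g and Cd3d by 3.437 and 3.051. This count restates the pattern, so it decides nothing on a changed share of T and NK lymphocytes among the sorted cells. The sort, with under 5% lymphocytes per the labels, would leave few such cells, and the ratios keep no levels from which a share could be estimated. That share and a change of expression within CD11c+ cells by genotype both stay open.

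MHC class II genes also moved from lower at day 7 to higher at day 14, with a median change of 1.439 over 14 genes. B cells hold much of these transcripts, but 20 B cell markers changed by a median of 0.207. The 95% bootstrap interval from 0.028 to 0.422 came from resampling the markers and holds no spread between mice. Without both arrays that stand apart the B cell median was 0.253 and passed. Both B cell medians lie far below 1.439. The ratios keep no levels, so B cell markers near background could change little even where the share of B cells changed. The medians therefore do not decide on a changed share of B lymphocytes, which stays open, and the gap was not tested over mice. A changed share of dendritic cells, whose markers changed by a median of 0.88, was not tested and stays open. So does an effect of the genotype on CD11c+ cells themselves.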

How the results depend on the processing

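The probe set of largest standard deviation, genes above the median standard deviation, both arrays that stand apart left out and both covariates were chosen after seeing the data; the other alternatives were chosen beforehand. No filter and a filter at the 50th percentile of brightness were not run as alternatives, since ratios keep no brightness and no filter became the reported choice. Without signal over background, dim and bright genes cannot be separated. Counts are in the order day 7, day 14, both days, time in wildtype, time in IFNAR-/- and change of the difference, unless named. The cause was not tested except where stated.

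Of the values that answer a comparison, 178 stayed on their side of the threshold or within 1.5 times, 70 counts moved further and 3 no longer passed. Some of the 178 could hardly change. Leaving out an array of the other day kept the interferon-stimulated median at -0.344 at day 14 and at -1.379 at day 7. Quantile normalization gave 571, 706, 699, 1844, 2156 and 604 genes, and the mouse number as a block, which pairs no arrays here, gave 418, 679, 616, 1228, 1974 and 325.

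Array weights gave 1882, 1899, 2221, 2688, 4576 and 1765 genes. Every probe set by itself counts probe sets, not genes, and adds those without a single gene symbol, so its counts are of another unit: 1867 at day 14, 1307 for both days, 2573 and 3906 for time and 926 for the change. At least 2-fold, a stricter rule by construction, left 233, 310, 181, 484, 705 and 296. Only the arrays compared, with fewer arrays for the spread, gave 317 at day 7, 362 at day 14 and 1155 for time in IFNAR-/-. Without both arrays that stand apart, time in wildtype gave 2428 and time in IFNAR-/- 1136.

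The 5' over 3' covariate gave 37 genes at day 14, 493 for both days, 154 for time in wildtype and 3 for the change. Its standard error for the same residual spread was 1.34 times larger at day 14 and for time in wildtype, and its slope rests mostly on the arrays at -0.913 and -0.52. The poly-A covariate gave 277 at day 7, 864 for time in wildtype and 184 for the change.

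Camera with an estimated correlation called 4, 0, 1, 0, 0 and 0 lists, and fry called 5 at day 14, 2 for both days, 12 and 9 for time. The interferon-stimulated median at day 14 was -0.125 with the poly-A covariate and did not pass; it was -0.344 with the estimated correlation and with fry, which change the test alone, and did not pass. A p that misses the threshold does not show that there was no difference.

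With each array left out in turn the genes ran from 210 to 703 at day 7, 384 to 913 at day 14, 376 to 1037 for both days, 716 to 2169 for time in wildtype, 1094 to 2520 for time in IFNAR-/- and 138 to 485 for the change. The interferon-stimulated median ran from -1.666 to -1.089 at day 7 and -0.448 to -0.205 at day 14, and Ifnar1 over both days from -0.726 to -0.376.

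Among named genes, 10 values changed sign, all of differences that had not passed. Cxcl10 at day 7 was 0.165 with the 5' over 3' covariate and ran from -0.552 to 0.423 with 1 array left out. Ifnar1 at day 14 was 0.011 with quantile normalization, 0.189 with array weights, 0.232 without both arrays that stand apart, and ran from -0.468 to 0.232. Ifnar2 at day 7 was 0.089 on the probe set of largest standard deviation and ran from -0.322 to 0.10. Nos2 over both days ran from -0.751 to 0.064.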

Other observations

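The count of neighbouring pairs among genes called at both days and the wider windows around Ifnar1 were chosen only after the result was seen; the other tests of this part were not.

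Other splits of the arrays were compared with the real ones. For comparisons of single groups 10 splits are too few for a share under 0.05. The real split gave 481 genes at day 7 and the highest other 1, 917 and 3 at day 14, 1451 and 0 for time in wildtype, and 2244 and 0 for time in IFNAR-/-. For the mean over both days 1 of 100 relabellings within days, the real one, gave as many as 762 genes, and the highest other drawn gave 94. Exchanging the genotypes at day 14 alone, which was not drawn, would give the 451 genes of the change, also fewer than 762. A chance labelling thus seldom gave that count. The relabellings also remove differences of single days, so they do not test a difference common to both days.

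Probe sets without a single gene symbol, 10092 in all, were tested by themselves in the same model. Of these 95 passed between genotypes at day 7, 159 at day 14 and 140 over both days, 268 and 388 over time in wildtype and IFNAR-/- cells, and 108 for the change of the difference.

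The 16 genes lower in IFNAR-/- cells at day 7 and higher at day 14, chosen after their values were seen, were Ccr7, Cd69, Cd74, Clec5a, Cx3cr1, Cxcl9, Gm8369, Grasp, Il2rb, Lap3, Ms4a4b, Nfkbie, Nr4a2, Rgs1, Rgs2 and Stat4.

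Genes beside an altered gene can stay those of the strain in which it was altered, which may change their signal on an array. Of 46 measured genes beside Ifnar1, as placed in assembly GRCm38.p6, 1 was called over both days (Atp5o, chosen after its value was seen), 2.17% against 4.19% of all genes. The one-sided Fisher exact p for an excess was 0.861, and a share below that of all genes argues against strain DNA as a cause of many calls among these 46. Among the nearest 25, 50 and up to 100 measured genes on each side, 2 of 50 (4%), 3 of 100 (3%) and 8 of 164 (4.88%) were called. Their one-sided Fisher exact p values were 0.625, 0.795 and 0.381. The widest window was cut at an end of the chromosome, so 1 side held fewer than 100. Kcnj15 is among the 3 and Mx1 among the 8, and for single genes such as these and Atp5o the explanation stays open.

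Stretches of DNA elsewhere could also differ between the breeding lines. Of the 51 genes called in the same direction at both days, 4 pairs lay within 10 measured genes of each other, against a mean of 1.4 in 10000 permutations (one-sided permutation p 0.0461). The pairs were Cd300ld with Cd300lf, Plekhf1 with Pop4, Pop4 with Zfp939 and Fbxl2 with Glb1. This is what such stretches need, but neighbours that are regulated together, as members of 1 gene family can be, would give the same and were not tested.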
